A study of Mus musculus with 2 samples.

How the data were processed

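CD45.1+ immune cells had been sorted by flow cytometry from the pancreas of female NOD/ShiLtJ mice, a strain that develops autoimmune diabetes spontaneously, at 7 or 12 weeks of age, and captured with the 10x Genomics Chromium 3' chemistry. Each age had 1 library. The number of mice behind a library is not given in the sources used here. The authors deposited, per library, a matrix of unique molecular identifier (UMI) counts per gene and cell barcode, made with Cell Ranger 1.3.1 on the mm10 build per the submitters' processing notes. The settings of its cell calling and the gene annotation's version are not given in the sources used here. The values were whole numbers with different totals per barcode, and 27998 genes were listed by Ensembl identifier and symbol. None of their symbols matched an immunoglobulin or T cell receptor gene, so clonotypes, isotypes and the immunoglobulin constant region list were not analysed here.

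Barcodes with at least 200 genes and at most 10% mitochondrial UMIs were kept, which left out 4 and 8. Scrublet, run per library, marked 2 of 1109 barcodes at 7 weeks (0.180%) and 8 of 2804 at 12 weeks (0.285%), under the 0.887% and 2.24% expected for these numbers of barcodes, and the marked barcodes were removed. Doublets therefore remain: 10 and 17 of the analysed cells held 2 or more UMIs of both Cd3e and Cd79a, the T and B cell receptor components. The remaining 1107 and 2796 cells were clustered together without batch integration: scaling to 10000 UMIs per cell, log transformation, 2000 variable genes without mitochondrial, ribosomal protein, receptor and Xist genes, 30 principal components, 15 neighbours and Leiden resolution 1.0, in scanpy 1.11.5 with Python 3.11.15. A cluster took a class name, written with "-like", from marker lists of 23 cell types fixed before the data were examined, when at least 2 markers of that type and of no other type as many were among its 10 leading genes by fold (genes in at least 25% of its cells) and at least 3 of its markers were each detected in 10% of its cells. Clusters that did not meet this kept their number.

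Some steps were set after the clusters had been seen: the thresholds for naming, the finer clustering (resolution 0.5, chosen after 0.5 and 1.0 had been viewed) of clusters 8 and 13, which separated cDC1-like, endothelial-like, plasma cell-like and B-like cells from them, and the rule that kept cluster 2 out of the NK-like class because its Cd3e level was over 200 CPM. The genes that lead a class were compared between the libraries within it. Sizes were compared only for classes in which at most 25% of leading genes had an interval excluding 1 and a ratio beyond 1.5-fold, a limit also set after the values had been seen. Nor were sizes compared where over 25% had a ratio beyond 1.5-fold whatever its interval, since with few UMIs an interval rarely excludes 1. Cells with over 2% of UMIs from acinar, endocrine, erythroid or stromal markers were likewise set aside as other-tissue cells. Classes and clusters with at least 50 cells in each library were compared within themselves. Cluster 8 held 46 cells at 7 weeks, under that minimum, and its cDC1-like cells were joined back, after the counts had been seen, to give 56 and 182.

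Shares of cells were given with exact Clopper-Pearson 95% binomial intervals and the 12 week over 7 week ratio with an exact conditional binomial interval. Raw UMI counts were summed per class and library and expressed as CPM, counts per 1000000 UMIs of the class sum, with the ratio and its exact interval. A gene at 0 in one library was given a ratio against a floor of 3 counts over the class, below called a bound. It leaves out the counting error of the other library, so the exact interval can reach lower. With 1 library per age there was no test. Intervals cover counting error only. Those of UMI ratios and list medians treat each UMI as independent and leave out variation between cells. A single cell with many UMIs can therefore carry such an interval away from 1. In 17 of the 120 entries named by rank, 1 cell held over 50% of the UMIs. Neither differences between mice nor between preparations can be measured, and age cannot be told apart from library. Gene lists (25, fixed before the data were examined) were summarised by the median log2 CPM ratio of members with at least 10 UMIs, 0.5 UMI being added to each sum, with an interval from 500 Poisson draws of the counts, and by the percentile of that median among 10000 random lists of equal size matched on UMI sum in 20 bins. The percentile describes these libraries. Limits of 2.5 and 97.5 for choosing the lists the text leads with were set after the values had been seen. Of 370 listed genes 15 had no entry in the matrices under those symbols.

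Genes were named by a rule fixed before the data were examined. Among genes with at least 30 UMIs in a class, leaving out mitochondrial, ribosomal protein, haemoglobin, receptor, acinar list and endocrine list genes and predicted or clone-named genes, those with the interval bound nearest to 1 farthest from 1 were named: 8 higher and 8 lower in the 3 largest classes, 6 and 6 in the others. From each list up to 4 measured members could be named, the 2 with most UMIs and the 2 farthest from 1, and Ptprc was given as a check of the sort. A gene outside this rule is named as chosen after its values were seen. A gene that the rule could have named was left out and is not reported here. For each named gene the ratio was also computed without the cell that held most of its UMIs. Where this turned the direction or moved a printed ratio or bound by over 1.5 times, the value without the cell is printed too. The same was done for summed acinar and endocrine transcripts with the cell that held most of them in each library. For genes named without a ratio, a share of over 40% of the UMIs in 1 cell is given. Shares of cells with a UMI were compared after each cell had been thinned to 1000 UMIs. The fewest UMIs in a barcode were 2587 and 3031, so no cell was left out by this. Gene types and positions were taken from GENCODE vM21 by gene identifier, an annotation that may differ from the authors'.

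The ratio and list calculations were tested on simulated data drawn from each class's own means and sums, with 200 genes changed per class among 3720 to 7463. The simulated counts were Poisson draws of class sums, the model the intervals assume, without variation between cells. The rates that follow therefore cover counting error alone and do not describe genes carried by a few cells. The intervals held the true ratio for 95.9% to 96.4% of unchanged genes, depending on the class. They excluded 1 on the right side for 94.0% to 100% of 4-fold changes, 58.8% to 88.1% of 2-fold changes and 36.2% to 56.1% of 1.5-fold changes. Of 100 simulated lists of 20 genes per class, 0 to 11 lay outside the percentile limits with no change, and 70 to 98 lay above them with every member 1.25-fold higher. Alternatives planned before the data were examined were: doublets kept, at most 5% mitochondrial UMIs, at least 500 genes, resolutions 0.5 and 2.0, 1000 variable genes, thinning before clustering, a class for each cell from its own marker score, TMM factors (edgeR 4.0.16) and median-of-ratios factors (DESeq2 1.42.0, R 4.3.3) on the class sums, means over cells, no minimum of UMIs, 1 UMI added, and thinning to 500 UMIs or none for shares of cells with a UMI. Others were added after the data had been seen: other-tissue cells kept, shares without B cells, the clusters within a class, other memberships of cluster 8 and its sub-clusters left out in turn, a finer cluster left out of cluster 0, ratios without the cell that held most UMIs of a gene or a sum, and, for the closing tests, thinned cells, cluster 3 without cells holding myeloid or B cell UMIs and the stress list without heat shock genes.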

Results

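Pancreas-infiltrating CD45.1+ immune cells of female NOD mice were profiled at 7 and at 12 weeks of age, to describe the immune cells that infiltrate the pancreas as autoimmune diabetes develops. The 7 week library held 1113 barcodes with 8701184 UMIs and the 12 week library 2812 with 19288252. Median depth was 5643 UMIs and 1800 genes per barcode at 7 weeks, and 4960.5 UMIs and 1613.5 genes at 12 weeks, with median mitochondrial shares of 1.97% and 2.03%. Each age had 1 library and no replicate, so every difference is between these libraries. Intervals are 95% and cover counting error only, leaving out variation between mice and, for UMI counts, between cells. Ratios are 12 weeks over 7 weeks. Positions are on mm10, from GENCODE vM21.

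Clustering separated B-like, CD8 T-like, CD4 T-like, regulatory T-like, cycling-like, macrophage-like, plasmacytoid DC-like, NK-like, ILC2-like, cDC1-like, plasma cell-like and endothelial-like cells, and several clusters that stayed unnamed. Clusters 0, 3 and 14 held Cd3e and Cd4 transcripts. Cluster 0 was led by Lef1, Ccr7 and Igfbp4, cluster 3 by Tnfsf8, Tnfsf11 and Il21, and cluster 14 by Lag3, Il10 and Il21. Cluster 2 was led by Ncr1, Xcl1 and Klra6, genes of innate lymphocytes, but held Cd3e at 421 CPM against 28.8 CPM in the NK-like cells. Cluster 8 was myeloid, led in its parts by Cd74 and by Ifitm or Fscn1 genes. The endothelial-like name rests on the 12 week cells, since the leading genes Emcn and Tm4sf1 had 0 UMIs in the 15 cells at 7 weeks. Ptprc, which encodes CD45, had UMIs in 92.8% of cells (interval 91.1% to 94.2%) at 7 weeks and 91.2% (90.1% to 92.2%) at 12 weeks.

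The makeup of the sorted cells was compared first. B-like cells formed a larger share at 12 weeks. They took 15.4% of cells (interval 13.3% to 17.6%) at 7 weeks and 23.03% (21.5% to 24.6%) at 12 weeks, a ratio of 1.4998 (interval 1.26 to 1.79). Cluster 0, the Cd4-positive cells led by genes of naive T cells, took 7.23% of cells (interval 5.77% to 8.91%) at 7 weeks and 13.5% (12.2% to 14.8%) at 12 weeks, a ratio of 1.87 (interval 1.46 to 2.41), and of 1.27 where cells were thinned to 1000 UMIs before clustering. Among innate-like lymphocytes, cluster 2 took 7.86% of cells (interval 6.34% to 9.60%) at 7 weeks and 3.11% (2.4996% to 3.82%) at 12 weeks, a ratio of 0.396 (interval 0.291 to 0.539). NK-like cells took 2.26% of cells (interval 1.47% to 3.32%) at 7 weeks and 0.644% (0.382% to 1.02%) at 12 weeks, a ratio of 0.285 (interval 0.147 to 0.544). Regulatory T-like cells took 7.95% of cells (interval 6.42% to 9.70%) at 7 weeks and 4.36% (3.64% to 5.19%) at 12 weeks, a ratio of 0.549 (interval 0.414 to 0.730). The ratio was 0.802 to 0.822 with fewer variable genes, thinned cells or a coarser clustering. Foxp3, their defining transcription factor, had a UMI in 2.17% of cells (interval 1.39% to 3.21%) at 7 weeks and 1.18% (0.814% to 1.65%) at 12 weeks after thinning to 1000 UMIs. In B-like cells, which should lack it, these were 0 of 170, which allows up to 1.76%, at 7 weeks and 0 of 644, which allows up to 0.466%, at 12 weeks at median depths of 4976 and 4597 UMIs. Unthinned, the Foxp3 shares were 8.04% and 3.97%. After thinning to 500 UMIs they were 0.542% and 0.536%. No difference was detectable at this depth for CD4 T-like cells (0.887, interval 0.681 to 1.16, and 0.664 with 1000 variable genes) and cycling-like cells (0.945, interval 0.698 to 1.29). The same held for cluster 8 without its cDC1-like and endothelial-like cells (1.34, interval 0.961 to 1.91, and 1.04 to 1.49 over the alternatives). Within these classes, 0 of 15 leading genes differed by over 1.5-fold between the libraries in B-like cells, 1 of 10 in cluster 0, 1 of 10 in cluster 2, 2 of 10 in NK-like and 2 of 10 in regulatory T-like cells. The sizes of CD8 T-like cells (6 of 17), cluster 3 (3 of 10), plasmacytoid DC-like (3 of 10), ILC2-like (4 of 10), macrophage-like (7 of 10), plasma cell-like (9 of 10) and endothelial-like cells (10 of 10) are not compared, because more of their leading genes differed. Nor are those of cluster 14, cDC1-like cells, cluster 13 and cluster 15, which was led by interferon response genes. Of their 10 leading genes 4, 3, 7 and 5 had ratios beyond 1.5-fold, and 2, 2, 2 and 1 of these an interval excluding 1, so too few UMIs were present to decide. These are shares of what passed a CD45.1+ sort and the cell calling, at 5643 against 4960.5 median UMIs, and not numbers of cells in the pancreas.

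**Figure D1:**
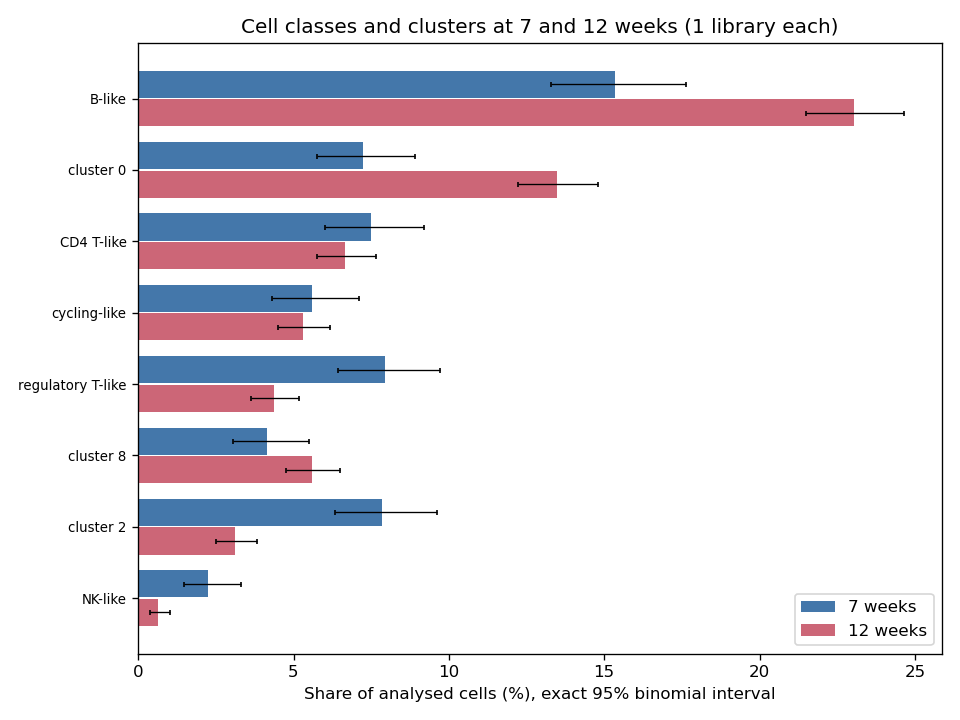
Share of analysed cells (x axis, percent of 1107 cells at 7 weeks and 2796 at 12 weeks) of each class or cluster whose size was compared (y axis), 1 bar per age with its exact 95% binomial interval; the other classes and other-tissue cells are not drawn. B-like cells take 15.4% and 23.03%, and cluster 2 7.86% and 3.11%.

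Transcripts of pancreatic parenchyma were found under the barcodes of the immune cells and were higher at 12 weeks. Whether this RNA lay inside the cells or free in the droplets was not tested. Summed acinar transcripts (digestive enzymes such as Prss2 and Ctrb1) were 3.19 to 18.5 times as high at 12 weeks in the 9 classes and clusters compared. Endocrine transcripts (islet hormones such as Ins2 and Gcg) were 3.31 to 6.35 times as high. Without the cell that held most of these UMIs in one library or the other, these ranges were 3.03 to 25.6 and 3.20 to 7.93. In B-like cells acinar transcripts were at 16.9 CPM at 7 weeks and 253 CPM at 12 weeks, and endocrine transcripts at 21.1 and 134 CPM. Erythroid transcripts had ratios of 0.631 to 1.07, and of 0.555 to 1.33 without such a cell. The list medians were positive in each class where they could be computed, from 1.40 to 3.64 for acinar (9 classes) and from 1.31 to 3.20 for endocrine transcripts (8 classes, with few members). With members at 0 UMIs in one library set at the floor of 3 counts, the acinar medians ran from 0.11 in cluster 0 to 3.30 in cluster 2 and the endocrine ones from 1.39 in CD8 T-like to 3.36 in cluster 3. In B-like cells this acinar median was 2.15, with 6 of 12 members at 0 in one library, as were 6 of 13 in cluster 0. With every detected member the acinar medians ran from 1.31 in cluster 8 to 3.55 in B-like and the endocrine ones from -0.12 in regulatory T-like to 1.95 in B-like, with 0.77 in CD4 T-like cells. With other-tissue cells kept in their classes, the acinar median was 5.34 in CD8 T-like cells and the endocrine median 10.62 in regulatory T-like cells. After thinning to 1000 UMIs, Prss2 was found in 0.632% of cells (interval 0.255% to 1.298%) at 7 weeks and 4.18% (3.47% to 4.99%) at 12 weeks. Ins2 was found in 0.271% of cells (interval 0.0559% to 0.790%) at 7 weeks and 4.43% (3.70% to 5.26%) at 12 weeks. Unthinned, these were 2.35% and 19.2% for Prss2, and 3.88% and 22.6% for Ins2. B-like cells, which make no insulin, held Ins2 in 0 of 170, which allows up to 1.76%, at 7 weeks and 25 of 644 at 12 weeks after thinning, at median depths of 4976 and 4597 UMIs, so a UMI of these genes is not read as expression by the cell.

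Besides the acinar transcripts, a pair of gene groups had medians on the same side of 0 in all 9 classes and clusters. For the immediate-early and stress genes these were below 0, from -0.48 in B-like cells to -0.21 in cluster 8, at or below percentile 0.02 of matched random lists. By their intervals 9 to 16 of the 18 to 20 members were below 1 and 0 to 3 above in a class. Hspa1b, an inducible heat shock chaperone, was at 0.312 of its 7 week level in B-like cells and 0.220 in cluster 2. The transcription factor gene Atf3 was at 0.0998 (interval 0.0243 to 0.309) in CD8 T-like cells. The transcription factor gene Jun, chosen after its values were seen, went the other way in CD4 T-like (1.248, interval 1.06 to 1.48), CD8 T-like (1.13, interval 1.03 to 1.253) and cluster 0 cells (1.17, interval 1.03 to 1.33). Medians of the MHC class I presentation genes were above 0 in each, from 0.11 in CD8 T-like to 0.32 in B-like cells, above the upper percentile limit in 3 of the 9. Members above 1 by their interval were 4 to 9 of 17, 4 in cluster 0, and members below 1 were 0 to 2. H2-Q4, which encodes a nonclassical heavy chain, was at 0.662 (interval 0.523 to 0.844) in cluster 0 and 0.653 (interval 0.564 to 0.757) in CD8 T-like cells. B2m (1.20) and H2-D1 (1.17, median ratio over the 9), which encode the light chain and a heavy chain, had intervals above 1 in each class, and kept that direction with TMM and median-of-ratios scaling. Of 3243 genes with at least 30 UMIs in each of the 9, 71 had intervals below 1 in each and 7 above 1 in each (Rps14, H2-D1, B2m, Ms4a6b, Rbm3, Eif4a1 and the acinar gene Ctrb1). The 71 included Ier5 (ENSMUSG00000056708, chromosome 1, 155096361 to 155099636), an immediate-early gene outside the fixed list (median ratio 0.204), the mitochondrial glutaredoxin Glrx5 (0.230) and the chaperone cofactor Bag1 (0.278). Pseudogenes were 18 of these 71 (25.4%) and 27 of all 3243 (0.833%). Among the 60 lower entries named by rank across the classes, 30 were genes of this set, so their lower level was not specific to a class.

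In B-like cells (170 and 644 cells), the MHC class I presentation, type I interferon response and glycolysis lists were higher at 12 weeks. The MHC class I list had a median log2 ratio of 0.32 (interval 0.23 to 0.39, percentile 99.6), and Tap2, a peptide transporter, was at 1.66 (interval 1.28 to 2.17). The type I interferon list was at 0.35 (interval 0.11 to 0.60, percentile 98.9), with Slfn5 at 2.77 (interval 1.20 to 7.86), and the interferon-gamma list at 0.15 (interval 0.088 to 0.39, percentile 76.9). Glycolysis was at 0.36 (interval 0.26 to 0.56, percentile 99.9), with Ldha, lactate dehydrogenase, at 1.51 (interval 1.297 to 1.76). The cell cycle list had a median of 0.58 (interval 0.27 to 0.93, percentile 99.99), with 16 of 23 measured members over 1.5 times higher and 3 with an interval above 1. This median was 0.28 as a mean over cells and 0.065 where each cell took a class from its own marker score. The class joins cluster 1 (155 and 566 cells) and part of cluster 13 (15 and 78 cells). In cluster 1 alone the cell cycle median was 0.22. The B cell activation list was at -0.20 (interval -0.27 to 0.014, percentile 0.225), an interval that includes 0, with 4 members below 1 by their interval and 2 above. Egr1 was at 0.695 (interval 0.547 to 0.889), Cd69 at 1.10 (interval 0.979 to 1.24) and Cd83 at 1.07 (interval 0.952 to 1.20). MHC class II genes, some of which lead this class, had a median of 0.20 (interval 0.17 to 0.25, percentile 81.4). The genes named by rank as higher were Cxcr3, the receptor of Cxcl9 and Cxcl10 (5.27 CPM at 7 weeks and 27.2 CPM at 12 weeks, 5.16, interval 2.13 to 16.3), the actin-severing protein Gsn (2.91, interval 1.97 to 4.46), the cholesterol synthesis enzyme Sqle (6.94, interval 1.82 to 58.9), Kat2a and Echdc1. Plod3, the acinar gene Sycn and the chemokine Ccl8 had 0 UMIs at 7 weeks, and Ccl8 had 45 UMIs in 41 cells at 12 weeks. Against the floor of 3 counts the 3 genes were 3.24, 6.20 and 4.16 times as high. Their lower interval bounds were 2.496, 4.90 and 3.25. Ccl8 was at 13.1 CPM there at 12 weeks, against 10.2 CPM in CD8 T-like cells and 12.9 CPM in cluster 0, so a UMI of it is not read as expression by the cell. The lower ones were Ier5 (0.168, interval 0.137 to 0.205), Rab11fip2, Bri3, Ing2, Hspa1b, Glrx5, Rab5a and Bag1. In these cells acinar transcripts were 15.02 and endocrine transcripts 6.35 times as high.

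In CD8 T-like cells (175 and 487 cells, in cluster 6, led by Dapl1 and Lef1, and cluster 9, led by Ccl5 and Nkg7), the inhibitory receptor genes Havcr2 and Lag3 were higher at 12 weeks and the cytokine gene Ifng was lower. Havcr2 (ENSMUSG00000020399, chromosome 11, 46454935 to 46481255), which encodes TIM-3, was at 8.79 CPM at 7 weeks and 31.9 CPM at 12 weeks, a ratio of 3.63 (interval 1.89 to 7.83), and Lag3 at 1.46 (interval 1.28 to 1.66). The activation and inhibitory receptor list as a whole was at 0.13 (interval -0.056 to 0.29, percentile 92.3), with Cd69 at 0.868 (interval 0.781 to 0.965). By their intervals 4 of its 18 members were above 1 and 3 below. The inhibitory receptor gene Pdcd1, which encodes PD-1, was at 0.884 without the cell that held most of its UMIs. That cell held 4.82% of them in the library where Pdcd1 was higher. No interval was computed for this value, so no difference is read from it. Ifng was at 214 CPM at 7 weeks and 139 CPM at 12 weeks (0.652, interval 0.555 to 0.768). The transcription factor gene Runx3 was at 0.701 (interval 0.612 to 0.805) and the Th1 list at -0.27 (interval -0.43 to -0.055, percentile 0.18). The cytotoxic granule protease gene Gzmb was at 0.594 (interval 0.471 to 0.751, and 1.14 without the cell holding 48.8% of its UMIs), the pore-forming protein gene Prf1 at 11.2 (interval 1.85 to 457). The IL-27 pathway list was at 0.35 (interval 0.14 to 0.47, percentile 99.9), with Socs3 at 1.46 (interval 1.15 to 1.87). The cell cycle list was at -0.25 (interval -0.37 to -0.012, percentile 1.23), and at -0.043 with marker-score classes. Cells high in cell cycle genes were clustered apart as cycling-like, a class with Cd8a at 375 CPM. The cell cycle median of CD8 T-like cells therefore describes only the cells left outside that class. Type I interferon genes were at -0.25 (interval -0.44 to -0.051, percentile 2.51). The cytotoxic list, which holds genes that lead cluster 9, was at 0.19 (interval 0.091 to 0.29, percentile 99.2). Several of these moved between the clusters. In cluster 6 alone the cytotoxic median was -0.58 and the IL-27 median -0.034, and in cluster 9 alone the cytotoxic median was 0.40 and the Th1 median -0.040. Ctla2a, which leads cluster 9, was at 0.372 in cluster 6 and 2.55 in cluster 9. Also named as higher were Tnip3 (4.26, interval 1.85 to 12.0), Pex10, Irgc1, Wdr91, Cpne4, the acinar gene Sycn and Ctla2a. Named as lower were Glrx5, Klra4, Ier5, Bag1, Tob1, Trib1, Hspa1b and Enah, of whose UMIs 1 cell held 77.8%. Ratios of summed acinar and endocrine transcripts were 4.91 (18.7 without the cell holding 73.8% of the 7 week sum) and 3.98.

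Cluster 0, Cd4-positive cells with naive T cell genes (80 and 377 cells), had higher levels of Il7r, the interleukin-7 receptor (1.64, interval 1.28 to 2.13), of Tnfrsf18, the costimulatory receptor GITR (1.70, interval 1.21 to 2.47), and of the surface protein gene Ly6a (1.93, interval 1.59 to 2.37) at 12 weeks. Of interferon-inducible genes, Gbp7 was at 2.07 (interval 1.35 to 3.30) and Gbp4 at 1.85 (interval 1.24 to 2.84). The interferon-gamma list, with 7 of 23 members over 1.5 times higher and 2 as much lower, was at 0.11 (interval -0.0033 to 0.41, percentile 87.2). The naive T cell list, which holds genes that lead the cluster, was at -0.0088 (interval -0.16 to 0.13, percentile 19.3). A finer cluster with 3 interferon-gamma list genes (Iigp1, Igtp and Gbp4) among its 10 leading genes, after naive T cell genes such as Lef1, held 3 of the cells at 7 weeks and 72 at 12 weeks. Without it the interferon-gamma median was -0.15, the type I interferon median -0.058 against 0.14 with it, and the ratio of Ly6a 1.302. The finer cluster was chosen by genes of the interferon-gamma list, so a fall of that median was built into the choice. The other genes named as higher, Nrm, C2cd5, Tsr1, Smyd4, Amica1, Ormdl2 and Cluap1, had 0 to 2 UMIs at 7 weeks. Against the floor of 3 counts the 5 at 0 were 2.31 to 3.08 times as high, with lower interval bounds of 1.77 to 2.39. The lower ones were Ier5 (0.173, interval 0.123 to 0.243), Glrx5, Tob1, Bag1, Smad7, Sik1, Rab24 and Hspa1b. Acinar transcripts were 8.76 (20.8 without the cell holding 58.3% of the 7 week sum) times and endocrine transcripts 5.18 (7.93 without the cell holding 35.7% of the 7 week sum) times as high in this cluster.

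Cluster 3, Cd4-positive cells led by Tnfsf8, Tnfsf11 and Il21 (151 and 265 cells), had higher interferon-gamma response genes at 12 weeks, with a median of 0.51 (interval 0.34 to 0.67, percentile 100) and 11 of 24 members over 1.5 times higher. Gbp2 (ENSMUSG00000028270, chromosome 3, 142620602 to 142638008), a guanylate-binding protein, was at 28.8 CPM at 7 weeks and 106 CPM at 12 weeks (3.68, interval 2.496 to 5.59). Gbp7 was at 2.60 (interval 1.59 to 4.43) and the proteasome subunit gene Psmb8 at 1.37 (interval 1.252 to 1.497). The type I interferon list was at -0.40 (interval -0.62 to 0.085, percentile 0.075), an interval that includes 0, with Isg15 at 0.620 (interval 0.493 to 0.779) and Ifit1 at 0.341 (interval 0.149 to 0.735), but Ifi27l2a, its most abundant member, at 1.24 (interval 1.18 to 1.31). The cytotoxic list was at 0.46 (interval 0.21 to 0.73, percentile 99.96), with the chemokine gene Ccl4 at 3.24 (interval 2.20 to 4.91, and 2.03 without the cell holding 37.5% of its UMIs) and Ctsw at 0.789 (interval 0.658 to 0.948). The regulatory T list was at 0.28 (interval 0.025 to 0.54, percentile 97.7), with Tnfrsf4, the costimulatory receptor OX40, at 1.61 (interval 1.41 to 1.84). Il7r was at 2.83 (interval 1.74 to 4.80), the transcription factor gene Tcf7 at 0.654 (interval 0.571 to 0.748), Nr4a1 at 0.349 (interval 0.268 to 0.451) and Tnf at 0.544 (interval 0.375 to 0.787). Markers of other cells were higher too: the myeloid gene Lyz2 at 5.71 (interval 3.27 to 10.8, and 3.23 without the cell holding 43.6% of its UMIs) and the B cell gene Cd79a at 5.19 (interval 2.67 to 11.3). These were named by rank with Cd74 at 3.92 (interval 3.16 to 4.90), Stfa3 at 5.89 (interval 2.83 to 14.2), the interferon-inducible Gbp2b (13.9, interval 4.53 to 69.2) and Spp1 at 163 (interval 28.9 to 6446). The 238 UMIs of Spp1 at 12 weeks lay in 22 cells, and whether those cells expressed it was not tested. Cells with a UMI of Lyz2, C1qa, Spp1, Cd79a or Ms4a1 were 30 of 151 at 7 weeks (19.9%) and 91 of 265 at 12 weeks (34.3%). Without them the interferon-gamma median was 0.33 (interval 0.16 to 0.52). Named as lower were Zfp771, Ier5 and Chic2, and Gal, Try10 and Ccl1, of whose UMIs a single cell held 100%, 100% and 77.6%. Endocrine transcripts were 4.10 times and acinar transcripts 5.04 times as high.

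In CD4 T-like cells (83 and 186 cells), the chemokine gene Ccl5 (ENSMUSG00000035042, chromosome 11, 83525778 to 83530518) was higher at 12 weeks, at 299.5 CPM at 7 weeks and 1463 CPM at 12 weeks (4.88, interval 4.10 to 5.86), found in 36 and 88 cells. The glucocorticoid-induced regulator gene Tsc22d3 was at 2.69 (interval 1.93 to 3.83) and Tnfsf8, which encodes CD30 ligand, at 2.69 (interval 1.69 to 4.48). Iws1, Pih1d1 and Il7r, a gene that leads this class, were also named as higher. The cytotoxic list had a median of 0.0073 (interval -0.24 to 0.33, percentile 55.9) and MHC class I genes 0.20 (interval 0.10 to 0.26, percentile 98.9). The naive T cell list was at -0.48 (interval -0.63 to -0.072, percentile 0.01). Where each cell took a class from its own marker score, the ratio of Ccl5 was 1.27, that of Tnfsf8 1.10, and the medians were 0.065 for MHC class I and 0.53 for naive genes. Named as lower were Ier5 (0.225, interval 0.149 to 0.335), Tmem160, Tob1, Glrx5, Smad7 and the epithelial gene Lgals7, of whose UMIs 1 cell held 57.1%. Endocrine and acinar transcripts were 5.92 and 14.9 times as high.

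In regulatory T-like cells (88 and 122 cells), which suppress immune responses, the Il10 level and the cytotoxic list median were lower at 12 weeks. The type I interferon list median was higher. Il10 (ENSMUSG00000016529, chromosome 1, 131019845 to 131024974), an immunosuppressive cytokine gene, was at 349 CPM at 7 weeks and 132 CPM at 12 weeks (0.376, interval 0.292 to 0.482, and 0.477 without the cell that held 22.6% of its UMIs). Its UMIs were found in 25 of 88 cells at 7 weeks and 30 of 122 at 12 weeks, so the shares of cells differed less than the sums. The cytotoxic list had a median of -0.73 (interval -0.87 to -0.42, percentile 0), with 7 of 13 members over 1.5 times lower, Ccl5 at 0.536 (interval 0.468 to 0.613) and Nkg7 at 0.684 (interval 0.596 to 0.784), but Gzma, found in 1 and 9 cells, at 12.9 (interval 2.03 to 536, and 7.21 without the cell holding 44.4% of its UMIs). Type I interferon genes were at 0.56 (interval 0.23 to 0.74, percentile 100), with Bst2 at 1.64 (interval 1.22 to 2.23) and Zbp1 at 1.64 (interval 1.21 to 2.24). Of 14 measured members 7 were over 1.5 times higher, and 4 had an interval above 1 and 0 below. The activation and inhibitory receptor list was at -0.15 (interval -0.31 to 0.064, percentile 2.25), with Tigit at 0.313 (interval 0.109 to 0.804) and Tnfrsf4 at 1.26 (interval 1.14 to 1.39). The cell cycle list was at -0.33 (interval -0.41 to 0.071, percentile 0.73). It describes only cells left outside the cycling-like class, which gathered cells high in these genes and had Foxp3 at 17.6 CPM. Where each cell took a class from its own marker score, the medians were -0.36 for the cytotoxic list, 0.21 for type I interferon genes and 0.077 for the cell cycle. As means over cells, the cytotoxic and activation medians were -0.43 and -0.029. The genes named as higher, Spp1, Clu, Dcn, Apoe, C3 and Cp, are genes of epithelial, stromal and myeloid cells and came from few cells: Spp1 was found in 3 cells, of which 1 held 86.5% of its UMIs. For the others 1 cell held 56.8% (C3), 76.4% (Cp), 77.0% (Clu), 80.3% (Apoe) and 99.0% (Dcn). Ier5 (0.184, interval 0.115 to 0.286), Dusp5, Habp4, Tmem160, Emsy and Ctage5 were named as lower. Ratios of 7.26 and 3.31 were found for acinar and endocrine transcripts.

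Cycling-like cells (62 and 148 cells) held both Cd8a and Cd4 transcripts and had higher cytotoxic, activation and follicular helper list medians at 12 weeks. By their intervals 11 of 19, 9 of 18 and 5 of 14 measured members of these lists were above 1, and 0 of each below. The cytotoxic list was at 0.46 (interval 0.34 to 0.70, percentile 100), with the chemokine gene Ccl3 at 3.39 (interval 2.72 to 4.26), the granzyme A gene Gzma at 2.60 (interval 2.18 to 3.11), or 1.74 without the cell holding 34.6% of its UMIs, and Ifng at 2.14 (interval 1.68 to 2.77). The activation and inhibitory receptor list was at 0.35 (interval 0.20 to 0.53, percentile 99.99), with Havcr2 at 4.09 (interval 1.96 to 9.86) and Lag3 at 1.94 (interval 1.64 to 2.29). The follicular helper list was at 0.50 (interval 0.29 to 0.65, percentile 100), with Maf at 1.90 (interval 1.41 to 2.59) and Cxcl13, a chemokine that attracts B cells, at 25.5 (interval 4.38 to 1026) in 17 cells. The naive list was lower (-0.40, interval -0.70 to -0.21, percentile 0.11), with Tcf7 at 0.780 (interval 0.652 to 0.935). Glycolysis was at 0.28 (interval 0.10 to 0.31, percentile 99.7), but with Hk2 at 0.364 (interval 0.221 to 0.595) and Pgk1 at 0.502 (interval 0.357 to 0.705). The cell cycle list, which defines the class, was at 0.20 (interval 0.13 to 0.24, percentile 98.5). As a mean over cells the activation median was 0.14 and the ratio of Gzma 1.24, and with classes from marker scores the activation and follicular helper medians were 0.16 and 0.29. Sostdc1, Tnfsf4, which encodes OX40 ligand, and Penk, which encodes proenkephalin (4.52, interval 2.54 to 8.72, 9.20 as a mean over cells and 2.44 with marker-score classes), completed the genes named as higher. Sostdc1 and Tnfsf4 had 0 UMIs at 7 weeks and were found in 8 and 13 cells. Against the floor of 3 counts they were 18.1 and 5.13 times as high, leaving out the counting error at 12 weeks. Sostdc1 was 10.2 times as high without the cell holding 44.2% of its UMIs. Bri3, Glrx5 and Ier5 were lower, and so were P3h3, Ncr1 and Lepr, of whose UMIs 1 cell held 72.7%, 94.6% and 86.7%. The class was not split by type of T cell, and its Cd8a and Cd4 levels, looked up after the other values had been seen, had ratios of 1.32 (interval 1.18 to 1.49) and 1.82 (interval 1.47 to 2.27). Its endocrine and acinar transcripts were 5.34 and 3.28 (6.64 without the cell holding 52.1% of the 7 week sum) times as high.

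Cluster 2, Ncr1- and Cd3e-positive lymphocytes (87 cells at each age), had a Th1 list median of 0.42 (interval 0.17 to 0.60, percentile 99.9) at 12 weeks, with 3 of 15 members above 1 by their interval and 1 below. The chemokine receptor gene Cxcr6 was at 1.249 (interval 1.05 to 1.49) and Ifng at 1.64 (interval 1.27 to 2.12, and 1.01 without the cell holding 39.3% of its UMIs), while the transcription factor gene Runx3 was at 0.748 (interval 0.578 to 0.966). Outside this list, the receptor gene Klrd1 was at 1.39 (interval 1.16 to 1.67). The costimulatory receptor genes Tnfrsf18 (1.93, interval 1.39 to 2.71) and Tnfrsf9 (3.48, interval 1.42 to 9.68), Il7r (1.70, interval 1.34 to 2.16) and the follicular helper list (0.66, interval 0.087 to 0.91, percentile 99.3, 5 members, Sh2d1a at 1.58, interval 1.12 to 2.25) were higher, and MHC class I genes were at 0.26 (interval 0.10 to 0.32, percentile 98.6). The cell cycle list was at 0.54 (interval 0.014 to 0.91, percentile 99.7), but Stmn1 was at 2.24 (interval 1.39 to 3.67, and 0.390 without the cell holding 83.3% of its UMIs) and Mcm7 at 2.24 (interval 1.16 to 4.50, and 1.13 without the cell holding 51.7% of its UMIs). Named as higher were Gadd45g (4.64, interval 2.94 to 7.59, and 2.65 without the cell holding 43.8% of its UMIs), Tbc1d15, Ms4a4b (1.74, interval 1.53 to 1.98), Rars, Gpr18 and Tsc22d3, and as lower Hspa1b (0.220, interval 0.148 to 0.319), Ier5, Tob1, AY036118, Tmem160 and Igfbp4, of whose UMIs 1 cell held 47.6%. Acinar transcripts were 18.5 and endocrine transcripts 4.22 times as high at 12 weeks.

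Cluster 8, myeloid cells with the cDC1-like cells joined (56 and 182 cells), had a cell cycle list median of 1.35 (interval 1.03 to 1.64, percentile 100) at 12 weeks, but of 0.19 without its sub-cluster 8.3, led by Fscn1. Besides the cDC1-like cells (10 and 26) the cluster pools sub-clusters 8.0 (20 and 48 cells), 8.3 (9 and 39) and 8.4 (17 and 69). In the whole cluster 21 of 24 members were over 1.5 times higher, among them the ribonucleotide reductase gene Rrm2 (5.51, interval 2.59 to 14.0, in 6 and 24 cells) and Stmn1 (2.18, interval 1.61 to 3.005). The complement and scavenger list was at 1.69 (interval 0.95 to 2.4995, percentile 100) over 6 members, and at 0.46 without sub-cluster 8.0, with the receptor gene Timd4 at 3.42 (interval 1.37 to 10.99) and C1qa at 5.98 (interval 2.66 to 16.7), or 1.22 without that sub-cluster, in 6 cells at 7 weeks and 17 at 12 weeks. In the macrophage-like cells, which express these genes, C1qa was at 3045 and 5847 CPM. The cytokine signalling inhibitor genes Socs3 (2.03, interval 1.499 to 2.81) and Socs2 (15.1, interval 4.06 to 127; 4.58 without sub-cluster 8.3) were higher. The interferon-inducible Gbp4 (0.397, interval 0.252 to 0.629) and Atf3 (0.381, interval 0.315 to 0.461) were lower, and Cxcl10 was at 0.516 (interval 0.429 to 0.623, and 1.46 without the cell holding 65.4% of its UMIs). MHC class II genes, some of which lead the cluster, were at 0.10 (interval 0.077 to 0.16, percentile 40.4). Also named as higher were Gpm6b, Meg3 (0 UMIs at 7 weeks, in 4 cells at 12 weeks), Ccl17 and Tm4sf5, of whose UMIs 1 cell held 43.4%, 76.7% and 52.8%, and as lower Ier5, Glrx5, Bri3, Tmem160, Bag1 and Hspb1 (0.126, interval 0.0515 to 0.280, and 1.45 without the cell holding 91.7% of its UMIs). Joining brought the cells at 7 weeks above the minimum of 50. With the endothelial-like cells joined too, the ratios of Ccl17 (49.0, interval 8.65 to 1948, and 11.5 without the cell holding 76.7% of its UMIs) and Gpm6b (17.4, interval 2.996 to 702) were 1.23 and 1.58. The 15 such cells at 7 weeks held 0 UMIs of the class's leading genes Emcn, Sparc and Tm4sf1 and 2 of Flt1. That name thus describes only the 11 at 12 weeks, and both higher ratios depend on leaving the endothelial-like cells out. Without the joined cells the interferon-gamma median, 0.23 (interval 0.079 to 0.30, percentile 97.6) with them, was -0.053, and the cell cycle median 1.99. Acinar transcripts were 3.19 times and endocrine transcripts 3.94 times as high.

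Across the classes, the medians of lists applied to several of them spanned the following ranges. The interferon-gamma response list ran from -0.025 in CD8 T-like to 0.51 in cluster 3, the lowest value turning positive with either other scaling. Type I interferon genes ran from -0.40 in cluster 3 to 0.56 in regulatory T-like, and glycolysis from -0.14 in CD4 T-like to 0.36 in B-like, cluster 2 turning negative with 1 other scaling. The IL-27 pathway ran from -0.032 in regulatory T-like to 0.35 in CD8 T-like and changed sign with scaling in B-like and CD4 T-like cells and cluster 3. The regulatory T list ran from -0.14 in CD8 T-like to 0.28 in cluster 3 and the follicular helper list from -0.092 in regulatory T-like to 0.66 in cluster 2. The Th17 list, with few measured members, ran from -0.62 in CD4 T-like to 0.47 in regulatory T-like and turned with scaling in cycling-like cells. The naive list ran from -0.48 in CD4 T-like to 0.073 in CD8 T-like and the cytotoxic list from -0.73 in regulatory T-like to 0.46 in cluster 3, both changing sign with scaling in cluster 0. In B-like cells the costimulatory ligand list was at 0.10, the germinal centre and plasma cell list at 0.025, negative with either other scaling, and the follicular, marginal zone and B1 list at 0.13. In cluster 8 the costimulatory ligands were at 0.61 without sub-cluster 8.4 and with it at 0.16, inflammatory cytokines and chemokines at 0.18 and the lipid-associated and phagocytic list at 0.072. Ptprc ratios lay between 0.962 and 1.249. Reads of near-identical copies, such as Hspa1a and Hspa1b, the H2-Q genes, Gbp2 and Gbp2b, the Klra genes or the trypsinogens, could be split between them, so values of single members are uncertain.

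**Figure D2:**
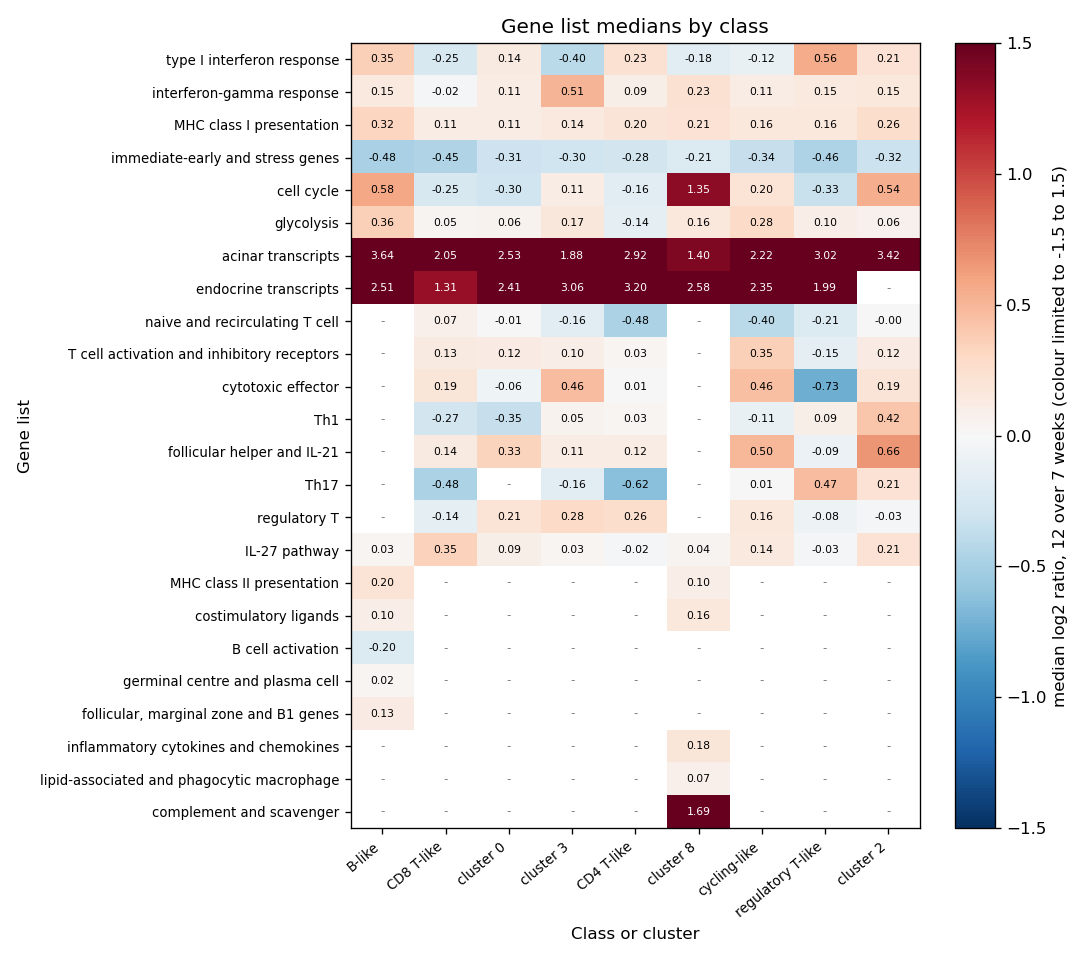
Median log2 CPM ratio, 12 over 7 weeks, of each fixed gene list (y axis) in each class or cluster compared (x axis). Colour runs from blue (lower at 12 weeks) to red (higher) and is limited to 1.5 either way, a dash marks a list not applied or with too few members, and the immediate-early and stress genes are negative and acinar transcripts positive in all 9 columns.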

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

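The limit of 2% used here was set after the clusters had been seen, and no explanation of these cells, which lay outside the comparisons of the report, was tested. A CD45.1+ sort should leave no parenchymal cells, but 15 of 2796 cells at 12 weeks (0.536%, above the 0.107% that a count of 0 allows) drew over 2% of their UMIs from acinar, endocrine, erythroid or stromal markers and were set aside. By the list with most UMIs, 5 were endocrine, 5 stromal, 3 acinar and 2 erythroid. At 7 weeks 2 of 1107 cells met the same limit (0.181%, under the 0.271% that a count of 0 allows), 1 endocrine and 1 erythroid. The ratio of these shares was 2.97 (interval 0.691 to 26.8), an interval that includes 1, so no difference between the libraries is shown. Most of the 12 week cells came from the cluster of the regulatory T-like class, which held 89 and 132 cells before this step and 88 and 122 after. Its share ratio was 0.587 with these cells and 0.549 without them.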

How the results depend on the processing

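The settings that keep other-tissue cells, take clusters of a class or parts of cluster 8 apart, leave out a single cell or a finer cluster, or leave B cells out of the denominator were chosen after the data had been seen. Differences inside the counting interval of the original value are called small here. Of 119 alternative values of 13 share ratios, 114 differed little and 5 more. Of 497 values of the 58 list medians at or beyond the percentile limits, 454 differed little, 38 more and 5 changed sign. For the other 80 medians these were 645, 31 and 2 of 678, and for 104 gene ratios 748, 33 and 4 of 785. In 8 shares of cells with a UMI, thinning to 500 UMIs or none moved 13 of 16 values, Prss2 at 12 weeks being at 2.003% and 19.2%. The share ratio stayed between 1.49 and 1.53 for B-like cells, 0.382 and 0.438 for cluster 2, 0.284 and 0.419 for NK-like cells and 0.548 and 0.822 for regulatory T-like cells over the alternatives that gave one. TMM and median-of-ratios factors shifted the median gene by at most 0.070 and 0.088 log2.

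The cause was not tested except where the membership of a class is what the setting changes. With 1000 variable genes the share ratio of CD4 T-like cells was 0.664 and that of regulatory T-like cells 0.804, at resolution 0.5 the latter was 0.822, and with cells thinned before clustering it was 0.802 and that of cluster 0 1.27. With classes from each cell's marker score, 13.4% of cells lying within 0.1 of another class, the cell cycle median was 0.065 in B-like, 0.25 in cycling-like and 0.077 in regulatory T-like cells. The stress list was at -0.32 in CD8 T-like and -0.68 in regulatory T-like cells, acinar transcripts at 3.06 in CD8 T-like cells, MHC class I at 0.065 and the naive list, with its sign changed, at 0.53 in CD4 T-like cells. The activation and follicular helper lists were at 0.16 and 0.29 in cycling-like cells, and type I interferon and cytotoxic genes at 0.21 and -0.36 in regulatory T-like cells. In B-like cells, cluster 1 alone gave 0.22 for the cell cycle list. In CD8 T-like cells, cluster 6 alone gave -0.32 for the stress list, 3.44 for endocrine transcripts and, with the sign changed, -0.58 for cytotoxic and -0.034 for IL-27 pathway genes and 0.372 for Ctla2a, while cluster 9 alone gave 0.40 for the cytotoxic and -0.040 for the Th1 list.

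Means over cells put the cycling-like medians at 0.31 for glycolysis, 0.61 for endocrine transcripts and 0.14 for the activation list. With 1 UMI added, acinar transcripts were at 3.04 in B-like cells and 1.59 in cluster 0. With members of at least 1 UMI, the Th17 list changed sign in CD8 T-like (0.025) and CD4 T-like cells (0.77) and endocrine transcripts in regulatory T-like cells (-0.12). Endocrine transcripts were at 1.40 in cluster 0, 1.40 in cluster 3, 0.77 in CD4 T-like cells, 0.93 in cluster 8 and 0.53 in cycling-like cells, and acinar transcripts at 1.84 in regulatory T-like cells, since members near 0 enter. With other-tissue cells kept, acinar transcripts were at 5.34 in CD8 T-like cells, and in regulatory T-like cells endocrine transcripts at 10.62, cell cycle at -0.54, activation at -0.43 and cytotoxic genes at -1.01. Cluster 8 with its endothelial-like cells gave 0.34 for interferon-gamma genes and 1.26 for Hspb1, above 1 in place of below. Without the cDC1-like cells these were -0.053 and 2.40, both on the other side, the stress list was at -0.32 and the cell cycle list at 1.99, and without its main cell Hspb1 was at 1.45. Without sub-cluster 8.3 the cell cycle list was at 0.19, without 8.0 the complement and scavenger list at 0.46 and without 8.4 the stress list at -0.45. Cluster 0 without its finer cluster gave -0.15 for interferon-gamma genes, 1.302 for Ly6a. Without the minimum of UMIs, 9 of 16 genes stayed named in B-like cells, 10 of 16 in cluster 0 and 5 of 12 in cluster 2. Small classes that an alternative clustering did not find again, and numbered clusters under marker scores, have no value there. No paired analysis was possible because each age had 1 library and the labels pair none. At this depth a 1.5-fold difference can go undetected. In simulations of counting error alone, the interval of such a gene excluded 1 on the right side for 36.2% of genes in cluster 0. It did so for 56.1% in regulatory T-like cells, these being the lowest and highest of the 9.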

Other observations

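The genes of the first 2 paragraphs, the test of gene copies, the readings of single classes in the tests of stress genes, the test without B cells and the questions about handling and sorting were chosen after the values had been seen; the other tests of this part were written before their results were. Macrophage-like cells (20 and 47 cells) were under the 50 cells per library that the comparisons required. Of their 10 leading genes 7 differed by over 1.5-fold between the libraries, such as C1qa (1.92) and Lyz2 (1.79). The cells under this name may therefore not be alike at the 2 ages. In them the chemokine Ccl8 was at 385 and 5118 CPM, 13.3-fold (interval 10.7 to 16.8) higher at 12 weeks, with UMIs in 2 of 20 cells at 7 weeks and 20 of 47 at 12 weeks. The ratio was 8.64 without the cell that held 37.4% of its UMIs. Cxcl13, which attracts B cells, had 0 UMIs at 7 weeks and 1324 at 12 weeks, at least 173-fold higher, but in 8 cells, and at least 53.3-fold without the 1 that held 70.8%. Cxcl9, a ligand of Cxcr3, was at 2283 and 3014 CPM (1.32-fold, interval 1.19 to 1.46), and Trem2 at 117 and 49.7 CPM (0.423-fold, interval 0.236 to 0.759, and 0.681 without the cell that held 40% of its UMIs). The cytokine subunit Il27 had 13 and 11 UMIs, 0.331-fold (interval 0.134 to 0.801), and 0.510 without the cell that held 38.5% of its UMIs.

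In the cDC1-like cells (10 and 26 cells), dendritic cells that present antigen to CD8 T cells, Cxcl9 was at 202 and 1336 CPM, 6.62-fold (interval 4.83 to 9.29), with UMIs in 5 of 10 cells at 7 weeks and 19 of 26 at 12 weeks. Cluster 14, the Cd4-positive cells led by Lag3, Il10 and Il21 (29 and 88 cells), had Ifng at 1280.5 and 574 CPM (0.448-fold, interval 0.373 to 0.538), but the ratio was 0.773 without the cell that held 44.2% of its UMIs, and UMIs were found in 16 of 29 cells at 7 weeks and 54 of 88 at 12 weeks, so the lower sum rests mostly on 1 cell. Il27ra in the same cells was at 113 and 185 CPM (1.64-fold, interval 0.995 to 2.81).

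Lower medians of the immediate-early and stress genes at 12 weeks were seen in all 9 classes and clusters. After every cell was thinned to 1000 UMIs the median over the 9 of the list medians was -0.31, and it was -0.12 in cycling-like cells. A difference in depth had been taken to need a value above -0.1. However, the ratios are already scaled to class sums, and thinning keeps each cell's expected proportions of genes. Thinning then only evens out the weight of deep cells, so this test cannot decide on depth. The median log2 ratio of shares of cells with a UMI was -0.22, where a few cells with very high values needed one above -0.05, but it reached only -0.12 in cycling-like cells, -0.097 in cluster 2 and -0.096 in cluster 0, where such cells stay open. Without the 7 heat shock members, which have near copies, the median over the 9 was -0.45, which argues against reads shared between such copies for the 9 together, though as a weak stand-in for reads assigned differently, and these stay open in cluster 0 (-0.20), CD4 T-like cells (-0.18) and cluster 2 (-0.13) and for the pseudogenes among the genes lower in all 9. Tissue handling or library preparation cannot be told apart from age, since there were 0 further libraries of either age, and a lower stress response with age may be the cause and was not tested.

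The higher interferon-gamma response genes in cluster 3 at 12 weeks may in part come from RNA of myeloid or B cells. Without cells that held a UMI of Lyz2, C1qa, Spp1, Cd79a or Ms4a1 the list median was 0.33, under the lower bound of the original interval (0.34) and so what this explanation needed, by a narrow margin and with its own interval of 0.16 to 0.52. Spp1 had 238 UMIs in 22 of the cluster's cells at 12 weeks, and its expression by these cells was not tested. The fall of the median therefore does not by itself show foreign RNA. Lyz2 stood at 74.3 and Cd79a at 48.2 CPM at 12 weeks, the CD45.1+ gate removes neither cell type, and the median stayed above 0, so foreign RNA is a candidate for part of the difference. After thinning to 1000 UMIs the median was 0.43, above that bound. Thinning keeps each cell's expected proportions of genes, so this cannot decide on a difference in depth. Exposure of these T cells to more interferon-gamma at 12 weeks stays open and was not tested.

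Cluster 2 and NK-like cells together were 112 of 1107 cells at 7 weeks (10.1%) and 105 of 2796 at 12 weeks (3.76%), a ratio of 0.371 (interval 0.282 to 0.489). Among cells outside B-like, plasma cell-like and cluster 13 the upper bound of the ratio was 0.541, so the larger B cell share at 12 weeks does not account for it. Without clusters, Ncr1 was found in 43 and 47 cells thinned to 1000 UMIs (unthinned, 8.67% and 2.79% of cells), with an upper bound of 0.670 for the ratio of shares, which argues against cluster borders or depth, and B-like cells, with median depths of 4976 and 4597 UMIs, had it in 1 of 170 and 0 of 644, the latter allowing up to 0.466%. Sorting or tissue handling of the 1 library per age cannot be told apart from age, with 0 further libraries. A smaller innate-like share in older NOD mice is a hypothesis, consistent with these values and untested by another animal.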
